A study of Mus musculus with 8 samples.

How the data were processed

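The study measured poly(A) RNA by directional RNA sequencing in 8 libraries of mouse E14 ESC and ESC-derived NPC, wild type and Wdr68 knockout, 2 per group. Per the submitters' notes, the authors aligned reads to mm9 with TopHat2 2.1.1 and estimated gene levels with Cufflinks 2.2.1. The deposited tables hold FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene, with a 95% confidence interval, and no counts. Each table had 24854 entries with 24318 symbols, and 285 symbols that filled 821 entries were summed. The 12 symbols whose estimate Cufflinks marked as failed in at least 1 library were left out (4930513N10Rik, Cbx5, Cnot1, Hnrnpr, Nono, Otud4, Prkd3, Sept7, Spast, Tnpo1, Zfp266 and Zfp281), which left 24306. No mitochondrially encoded gene was listed. The tables carry no p-values or ratios, and no file of reads was analysed here. A reference annotation of GRCm38 served only for names and for transcript GC content, and positions are those of the tables.

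Depth was inferred from the tables. The upper confidence bound of a gene with 1 start site lies above its FPKM by 2 square roots of its fragment number, so a fragment number follows from each pair of values. For genes with fewer than 5 implied fragments, these numbers were within 0.05 of a whole number in 66.9% to 71.6% of cases per library, against 10% by chance. The sums over all genes of a library are given as its depth. They include genes with several start sites, for which this relation was not checked. Small RNA genes took 25.1% to 41.4% of the summed FPKM, as their short length inflates FPKM. Without them, ribosomal protein genes took 21.0% to 25.5%, replication-dependent histone genes 0.064% to 0.157%, and the 10 highest genes 6.91% to 8.45%.

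The tests, gene lists, naming rule and most alternatives were chosen before the data were examined. Genes with FPKM of at least 1 in at least 2 libraries (13318) were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with 4 group means, a variance trend and 4 residual degrees of freedom. The 5 contrasts were knockout against wild type in ESC and in NPC, NPC against ESC in wild type and in knockout, and the difference between the knockout effects. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 per contrast. A 2-fold change means a log2 change of at least 1 in FPKM + 1, in either direction. This understates the change in level of genes with low FPKM. Chance for genes called in both of 2 contrasts was the product of their counts divided by the genes tested, per direction. The size of the differentiation response was the major-axis slope across genes. With 2 libraries per group, no test of single outlying libraries was possible, and splits of the libraries into other groups were not counted.

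Camera with a preset inter-gene correlation of 0.01 tested 29 gene lists per contrast, adjusted over the 29. They were general, naive, and formative and primed pluripotency; neural progenitors, postmitotic neurons, and synapse and axon guidance; retinoic acid response, Hox groups 1 to 5 and Hox groups 6 to 13; neural crest, mesoderm, cardiac muscle, definitive endoderm, extraembryonic endoderm and trophoblast; germline genes, the PRC1-AUTS2 complex, other Polycomb subunits, and WDR68-binding kinases with the CUL4 ligase. The rest were p53 targets, cell cycle, imprinted genes, Wnt targets, FGF-ERK targets, Notch targets, and hypoxia and glycolysis, with feeder fibroblasts, endothelium and blood, and astrocytes and oligodendrocytes as other cell types. Of the 489 list entries, 488 matched by symbol and 1 by a synonym. Camera with an estimated correlation and fry, which asks whether a list moves without comparing it with other genes, were the alternatives. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom, and with the preset one to the number of genes. Its p-values are larger for this reason too, so a lost call does not show that a list did not move. Some genes are in more than 1 list. The list of Notch targets also holds ligand and receptor genes (Dll1, Dll3, Jag1, Notch1 and Notch3), so it does not measure Notch activity alone.

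The text names, per contrast, the 8 genes with the largest rise and the 8 with the largest fall among those that passed. Mean FPKM had to be at least 5 in the higher group. Both libraries of a group had to lie on one side of the other group, except for the difference between stages, where this was not asked. Predicted genes, microRNA, small nucleolar RNA and histone genes were left out of this ranking. Per list it names up to 4 called members with the largest change, or the 1 or 2 with the smallest p. Dcaf7, Auts2, Pcgf3, Pcgf5, Rnf2, Pou5f1, Nanog, Sox2, Nes, Pax6 and Tubb3 are named in every case.

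Alternatives were a pseudocount of 0.1, no filter, an FPKM minimum of 5, median-ratio scaling, quantile normalization, the highest entry per symbol, fits of only the groups compared, the replicate number as a block, no variance trend, a 2-fold minimum, and leaving out each library in turn. In the last, 3 residual degrees of freedom remained, and a lone library was assumed to vary like the other groups. Short RNA genes left out before the fit, and the imprinted list with Peg10 and Sgce counted once, were added after seeing the data.

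The procedure was tested on simulated data, with changes of known size added to 100 genes per size, drawn from those above an FPKM of 5. In ESC, 87% of genes changed by 1 on the log2 scale and 98% of those changed by 2 were called in the right direction, and 6.09% of calls were unchanged genes. The values were 83%, 98% and 5.73% for NPC, and 67%, 92% and 9.14% for the difference between stages. Camera called the list shifted by 0.5 in each. Noise was drawn independently for each gene from a normal distribution, so correlation between genes was not simulated. Nor were the discrete noise of genes with few fragments and a spread that differs between groups, as each gene had 1 spread for all 8 libraries. The rates above cover none of these. Other steps used Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures matplotlib 3.10.9.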

Results

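RNA from mouse E14 embryonic stem cells (ESC) and from neural progenitor cells (NPC) derived from them was sequenced in wild-type cells and in cells labelled as knockout for WDR68. WDR68 is a WD40-repeat protein that the series links to the PRC1-AUTS2 Polycomb complex, to the activating role of that complex and to the differentiation of stem cells. The tables list its gene as Dcaf7. NPC were made in hanging drops of 500 cells for 2 days, followed by 2 days in suspension and 4 days with retinoic acid. The 4 groups were wild-type ESC, knockout ESC, wild-type NPC and knockout NPC, with 2 libraries in each. The error intervals in the tables implied 5996677 to 7942644 fragments per library. Genes near an FPKM (fragments per kilobase of transcript, scaled to library size) of 1 rested on a median of 20 to 30 fragments. Between 10870 and 10942 genes reached an FPKM of 1 in the ESC libraries, 12209 and 12122 in the wild-type NPC libraries, and 11815 and 11886 in the knockout NPC libraries.

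Across genes, which are not independent replicates, the 2 libraries of a group correlated at r = 0.950 to 0.962 on the log2 scale. The mean r between groups was 0.961 for wild-type and knockout ESC and 0.908 for wild-type and knockout NPC. It was 0.737 for wild-type ESC and NPC and 0.760 for knockout ESC and NPC. The series states that samples were sequenced in duplicate and does not say whether the duplicates were separate cultures, so the p-values below measure only the spread between these libraries, which may be technical. Levels are given as mean FPKM ± SD (n = 2 libraries), and changes as log2 ± standard error from limma (4 residual degrees of freedom over 8 libraries), with the adjusted p over 13318 genes.

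Dcaf7 RNA was lower in both knockout groups, and some of it remained. The gene lies on chromosome 11 from 105898186 to 105920637 (mm9). Its level was 13.3 ± 1.27 in wild-type ESC and 2.53 ± 0.383 in knockout ESC, a log2 change of -2.02 ± 0.12 (adjusted p = 0.0011). In NPC the level was 28.4 ± 1.73 in wild type and 8.68 ± 0.443 in knockout, a change of -1.60 ± 0.12 (adjusted p = 1.3e-04). All 4 knockout libraries lay below all 4 wild-type libraries. Dcaf7 RNA rose on differentiation in both genotypes, by 1.04 ± 0.12 in wild type and 1.46 ± 0.12 in knockout. The difference between the knockout effects in the 2 stages did not pass (0.42 ± 0.17, adjusted p = 0.135).

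**Figure D1:**
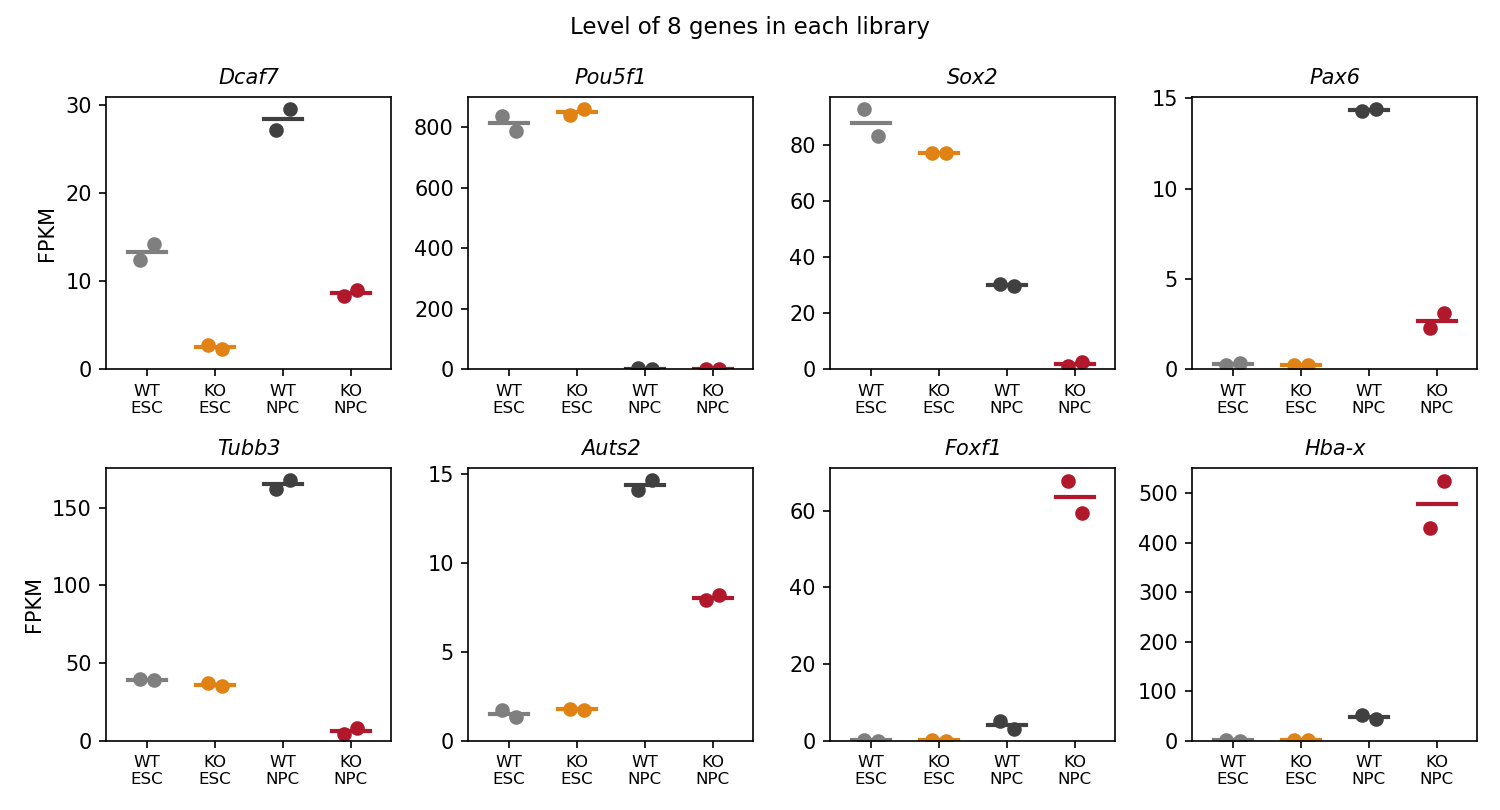
Levels of 8 genes in each library, in FPKM on axes that start at 0. Points are libraries and lines are group means. Dcaf7 was low in both knockout groups, Sox2, Pax6 and Tubb3 were low in knockout NPC, and Foxf1 and Hba-x were high there.

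Knockout and wild-type stem cells were compared to find what the knockout changes before differentiation. Few genes changed. No member of the general or naive pluripotency lists passed, and 4 imprinted genes were among those that passed. At an adjusted p under 0.05, 33 genes passed, 17 higher and 16 lower. Of 13318 genes, 1686 had an unadjusted p under 0.05, more than chance alone would give. With 2 libraries per group, smaller changes may have been missed, so 33 is not the number of genes that changed. Pou5f1 stood at 813 ± 36.1 in wild type and 849.9 ± 12.3 in knockout, and Nanog at 427 ± 8.51 and 411 ± 6.23. Sox2 was at 88.1 ± 6.81 and 77.5 ± 0.0110. None of these 3 passed (log2 change 0.07, -0.06 and -0.18; adjusted p = 0.927, 0.958 and 0.761). Nor did Auts2 (1.51 ± 0.289 and 1.75 ± 0.0167), Pcgf3, Pcgf5 or Rnf2 (adjusted p = 0.679, 0.529, 0.467 and 0.635), or the neural genes Nes, Pax6 and Tubb3 (adjusted p = 0.295, 0.929 and 0.868).

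Among the genes that rose in knockout ESC, Sgce went from 1.63 ± 0.0234 to 7.42 ± 2.29 (1.65 ± 0.17, adjusted p = 0.0214) and its neighbour Peg10 from 32.0 ± 4.67 to 73.7 ± 4.22 (1.19 ± 0.11, adjusted p = 0.0106). Otx2, a gene of the formative state, went from 1.47 ± 0.478 to 5.68 ± 0.828 (1.44 ± 0.16, adjusted p = 0.0286). The meiotic cohesin gene Rec8 rose by 1.19 ± 0.10, Slc25a4 by 0.99 ± 0.07, Snrpn by 0.86 ± 0.07, B9d1 by 0.75 ± 0.09 and Gja1 by 0.71 ± 0.08. Apart from Dcaf7, the changes of the genes that fell were -1.44 ± 0.17 for Calb2, -1.32 ± 0.16 for Grb10 (6.06 ± 0.0948 to 1.84 ± 0.178), -1.07 ± 0.11 for Gstp2, -0.97 ± 0.12 for Gstp1, -0.90 ± 0.10 for Mt2, -0.86 ± 0.11 for Klhl22 and -0.59 ± 0.07 for Cetn3. Gstp1 and Gstp2 are neighbouring paralogs. In each of these genes both knockout libraries lay on the same side of both wild-type libraries. Outside this ranking, and named after their values were seen, the paralogs Zscan4a, Zscan4c and Zscan4f also passed, each lower (-1.03, -1.17 and -1.25).

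Most of these calls rested on every library. Fits of only the ESC groups called 3 genes, the short RNA genes Mir3062, Snora21 and Snord34, named after their values were seen and not among the 33, and Dcaf7 there had an adjusted p of 0.270. With a library left out, 10 genes passed without wild-type ESC replicate 1, 13 without replicate 2, 16 without knockout ESC replicate 1 and 15 without replicate 2. Of the 17 genes the naming rule gave that passed, 2 kept their call whichever library was left out, namely Dcaf7 and Slc25a4. Peg10 lost it without either knockout ESC library (adjusted p 0.0144 to 0.0863 over the libraries left out) and Sgce without either wild-type ESC library (0.0029 to 0.146). Gstp1 (0.0283 to 0.198) and Gstp2 (0.0317 to 0.146) kept it only without knockout ESC replicate 2. Otx2 (0.0556 to 0.206), Rec8 (0.0556 to 0.0852), Snrpn (0.0825 to 0.105), Grb10 (0.184 to 0.213), Calb2 (0.175 to 0.218), B9d1 (0.105 to 0.219), Gja1 (0.0883 to 0.172), Mt2 (0.146 to 0.164), Klhl22 (0.0901 to 0.218) and Cetn3 (0.170 to 0.230) lost it without any of the 4. Of the 33 genes, 7 were microRNA or small nucleolar RNA genes. These and the 13 called in NPC rested on a median of 2.50 implied fragments in the higher group.

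Of the 29 gene lists, camera called 2 in knockout ESC, and neither call held with an estimated correlation. In the imprinted list, 3 of 20 tested genes rose, 1 fell and 16 did not pass, with 9 rising and 3 falling when adjusted over the list alone. The list lay higher as a whole (camera adjusted p = 0.005, and adjusted p = 0.269 with an estimated correlation). With Peg10 and Sgce, which share an imprinted cluster, counted once, an alternative chosen after seeing the data, these values were 0.0427 and 0.649. None of 11 germline genes passed over all genes, while 0 rose and 7 fell when adjusted over the list alone, and the list lay lower (median -0.45, camera adjusted p = 1.2e-04, and adjusted p = 0.246 with an estimated correlation). Its members with the smallest p were Hormad1 (-1.01 ± 0.16, adjusted p = 0.0855) and Ddx4 (-0.54 ± 0.11, adjusted p = 0.162). The lowest adjusted p among the other 27 lists was 0.0508, for the hypoxia and glycolysis list, which passed with median-ratio scaling (adjusted p = 0.0445). For 9 of the uncalled lists, with medians from -0.04 to 0.04, the median, mean and test direction differed in sign or the median was 0.

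The same comparison in NPC asked what the knockout does after differentiation. In the neural progenitor list 18 of 23 genes fell, a call that held (adjusted p = 0.0310 with an estimated correlation). In the neuronal list 23 of 25 fell and in the endothelial and blood list 9 of 11 rose, and both calls were lost (adjusted p = 0.0512 with an estimated correlation for each). These values lie close to that of the neural progenitor list, so they do not show that neuronal genes changed less. Fry called 24 of the 29 lists in this comparison. In all, 3648 genes changed, 1962 higher and 1686 lower. Of these, 1038 changed by 2-fold or more in FPKM + 1, 312 higher and 726 lower (1393, 461 and 932 with a pseudocount of 0.1). With median-ratio scaling 3346 genes changed in all, 1377 higher and 1969 lower, so the side with more genes depended on the scaling. The larger falls outnumbered the larger rises under both scalings. The count was 2281 without knockout NPC replicate 1 and 2418 without knockout NPC replicate 2.

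Among the 8 deepest falls were Tubb3 and Stmn2 of the neuronal list and Fabp7 of the neural progenitor list. Miat went from 72.1 ± 5.24 to 1.18 ± 1.14 (-5.17 ± 0.32, adjusted p = 7.2e-05), Msx3 from 65.9 ± 8.13 to 1.40 ± 1.63 (-4.99 ± 0.42) and Fabp7 from 87.1 ± 3.15 to 2.40 ± 0.534 (-4.70 ± 0.32). The neuronal tubulin gene Tubb3 went from 165 ± 3.70 to 6.13 ± 2.42 (-4.58 ± 0.20, adjusted p = 2.0e-05) and Stmn2 from 52.3 ± 9.69 to 1.35 ± 0.0283 (-4.49 ± 0.12). Cdkn1c (-4.63 ± 0.15), Ckb (-4.43 ± 0.13) and Tagln3 (-4.36 ± 0.31) fell by similar amounts. Unlike the others of the 8, Stmn2 (78.1 ± 0.421) and Ckb (171 ± 10.9) stood higher in wild-type ESC than in wild-type NPC (126 ± 11.6 for Ckb). Their RNA was therefore not particular to neural cells in these data. Sox2 went from 30.2 ± 0.311 to 1.81 ± 0.934 (-3.51 ± 0.20, adjusted p = 4.9e-05) and Pax6 from 14.3 ± 0.0814 to 2.69 ± 0.587 (-2.06 ± 0.14, adjusted p = 9.7e-05). Nes, another progenitor gene, did not pass (30.0 ± 0.287 and 23.9 ± 2.12, -0.32 ± 0.11, adjusted p = 0.0786). Auts2 went from 14.4 ± 0.425 to 8.03 ± 0.232 (-0.77 ± 0.12, adjusted p = 0.0034).

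Among the 8 largest rises were 3 globin genes, the transcription factor gene Foxf1 and the short RNA gene Rnu11. Foxf1 went from 4.11 ± 1.41 to 63.6 ± 5.89 (3.69 ± 0.19, adjusted p = 3.9e-05), and the neighbouring noncoding RNA gene Fendrr from 1.42 ± 0.574 to 25.9 ± 0.346 (3.50 ± 0.17). The embryonic globin genes Hba-x (47.4 ± 6.75 to 478 ± 67.1, 3.31 ± 0.16) and Hbb-bh1 (24.3 ± 7.64 to 233 ± 38.4, 3.24 ± 0.36) rose, as did Grin2c (3.34 ± 0.14) and Sh3bgr (3.15 ± 0.17). In each of these genes, and in those that fell, both knockout libraries lay on one side of both wild-type libraries. The globin gene Hba-a1 passed (4.70 ± 1.40, adjusted p = 0.0457) but stood at 39.4 and 0.265 in the wild-type NPC libraries, and kept its call only without wild-type NPC replicate 1 (adjusted p 0.0014 to 0.187). The short U11 RNA gene Rnu11 was listed at 0 in both wild-type NPC libraries and at 35.7 and 100.2 in knockout NPC, and also at 41.7 in 1 wild-type ESC library, and its call was lost without any of the 4 NPC libraries (adjusted p 0.0721 to 0.129).

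Of 23 neural progenitor genes tested, 18 fell, 2 rose and 3 did not pass (21 fell and 2 rose when adjusted over the list alone), among them Fabp7, Hes5 (-3.58 ± 0.16), Zic1 (-3.43 ± 0.15) and Dll1 (-3.38 ± 0.13). This was the single list in knockout against wild-type NPC whose call held with an estimated correlation (camera adjusted p = 2.9e-13, and adjusted p = 0.0310 with an estimated correlation). Of 25 genes of postmitotic neurons, 23 fell, 1 rose and 1 did not pass (23 and 2 adjusted over the list alone), with Stmn3 (-4.08 ± 0.24) and Ina (-4.05 ± 0.17) beside Tubb3 and Stmn2 (camera adjusted p = 2.1e-20, and adjusted p = 0.0512 with an estimated correlation). In the synapse and axon guidance list 9 of 18 fell, among them Cntn2 (-3.26 ± 0.14) and Dcc (-2.99 ± 0.12), and 3 rose, with 6 not passing and the same counts adjusted over the list alone (camera adjusted p = 0.0039, and adjusted p = 0.109 with an estimated correlation). No member of the Notch list rose, and 7 of 11 fell, also when adjusted over the list alone, among them Nrarp (-2.94 ± 0.24) and the ligand gene Dll3 (-2.67 ± 0.14; camera adjusted p = 2.6e-05, and adjusted p = 0.0512 with an estimated correlation). Hes5, Dll1 and Dll3, which fell, are also in the neural progenitor list, so the lists are not independent. Of 14 Wnt targets, 7 fell, among them Nkd1 (-2.21 ± 0.12), and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0039, and adjusted p = 0.265 with an estimated correlation).

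Hox genes of groups 1 to 5 mostly fell moderately, 9 of 15, while 3 rose and 3 did not pass (10 and 3 adjusted over the list alone; camera adjusted p = 8.1e-04, and adjusted p = 0.0756 with an estimated correlation). Hoxd4 (-2.68 ± 0.10) and Hoxd3 (-2.67 ± 0.21) changed most. In groups 6 to 13, 11 of 16 fell, 1 rose and 4 did not pass (11 and 2 adjusted over the list alone; camera adjusted p = 1.7e-05, and adjusted p = 0.113 with an estimated correlation). Hoxb9 went from 193 ± 1.91 to 14.1 ± 6.36 (-3.75 ± 0.26) and Hoxa6 fell (-3.13 ± 0.22), whereas Hoxb13 rose from 3.38 ± 0.447 to 27.6 ± 1.15 (2.71 ± 0.29). Neural crest genes fell in 8 of 13 cases and rose in 1, with the same counts adjusted over the list alone, and Pax3 (-3.17 ± 0.30) and Ednrb (-2.77 ± 0.18) changed most (camera adjusted p = 2.5e-04, and adjusted p = 0.174 with an estimated correlation). Hypoxia and glycolysis genes fell in 8 of 13 cases and none rose (10 and 0 adjusted over the list alone), among them Slc2a1 (-1.72 ± 0.16) and Bnip3 (-1.48 ± 0.15; camera adjusted p = 4.2e-05, and adjusted p = 0.173 with an estimated correlation).

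Of 11 endothelial and blood genes, 9 rose and 0 fell (10 and 0 adjusted over the list alone), among them Hbb-y (3.03 ± 0.19) and Tal1 (1.96 ± 0.14; camera adjusted p = 8.6e-07, and adjusted p = 0.0512 with an estimated correlation). Mesoderm genes rose in 8 of 11 cases and fell in 1, with the same counts adjusted over the list alone, and Tcf21 (2.34 ± 0.13), Foxc2 (1.47 ± 0.19) and Hand2 (1.25 ± 0.18) rose while Lhx1, which is also a neuronal gene, fell (-2.87 ± 0.16; camera adjusted p = 0.0039, and adjusted p = 0.0985 with an estimated correlation). With a pseudocount of 0.1 the mesoderm call was lost (adjusted p = 0.0764). Of 7 heart muscle genes, 4 rose and 0 fell (6 and 0 adjusted over the list alone), with Tnnt2 from 0.254 ± 0.0171 to 5.81 ± 0.414 (2.44 ± 0.11; camera adjusted p = 6.0e-04, and adjusted p = 0.0872 with an estimated correlation). Cell cycle genes rose slightly in 15 of 22 cases and none fell (18 and 0 adjusted over the list alone, median 0.31), among them Mcm5 (0.68 ± 0.07) and Cdk1 (0.62 ± 0.07; camera adjusted p = 1.8e-06, and adjusted p = 0.0512 with an estimated correlation). Of 18 p53 targets, 8 rose and 0 fell (13 and 1 adjusted over the list alone), led by Trp53inp1 (1.17 ± 0.08; camera adjusted p = 2.6e-04, and adjusted p = 0.0629 with an estimated correlation). Feeder fibroblast genes fell in 7 of 15 cases and rose in 2 (7 and 3 adjusted over the list alone), among them Lum (-1.72 ± 0.20; camera adjusted p = 0.0474, and adjusted p = 0.456 with an estimated correlation), and lost the call with median-ratio scaling (adjusted p = 0.105).

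**Figure D2:**
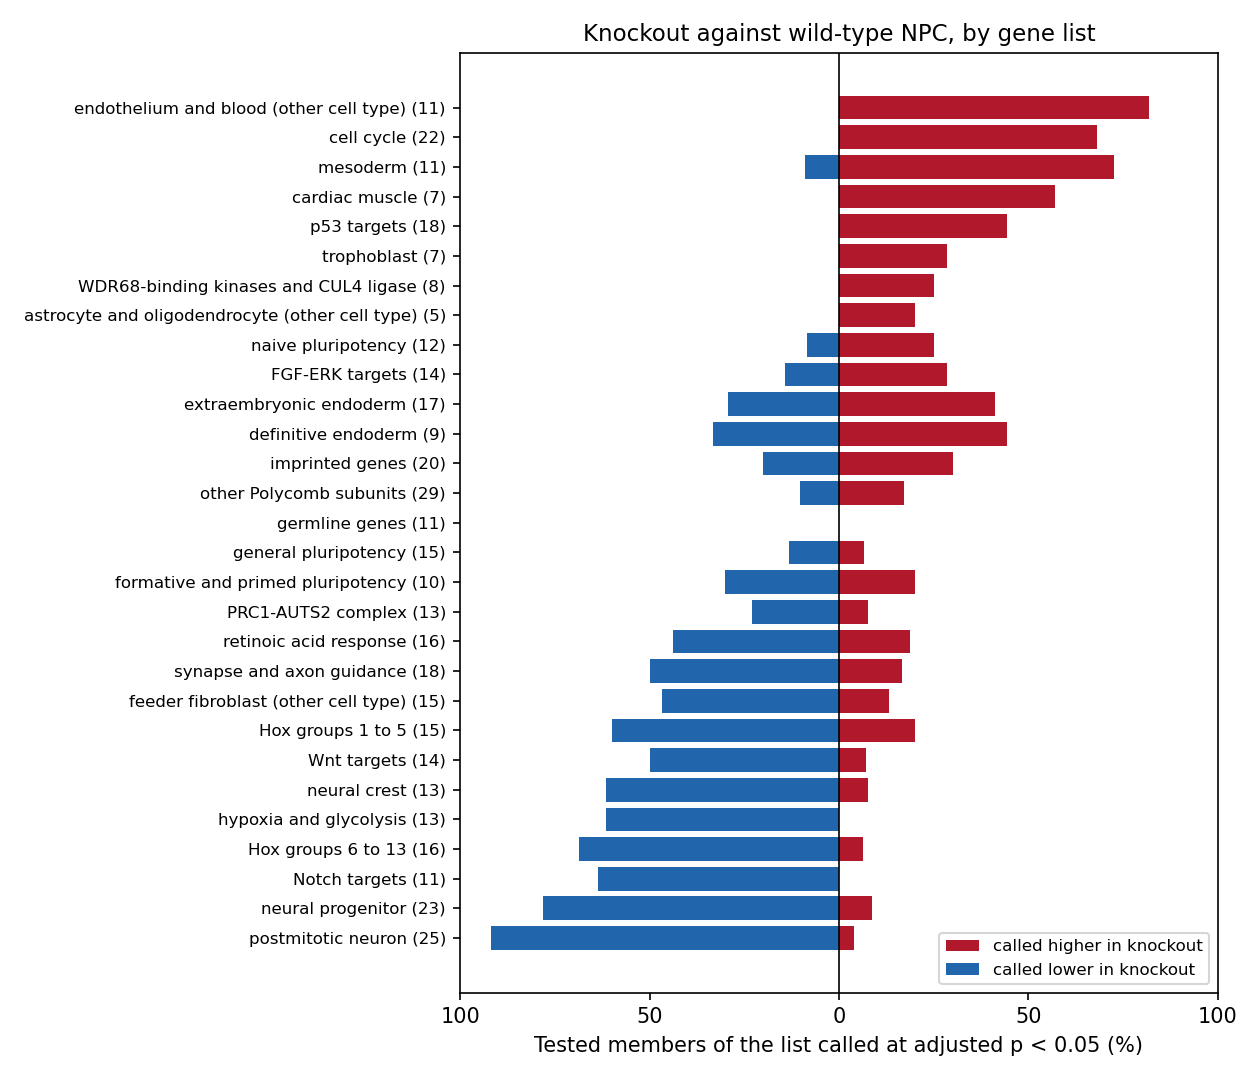
Percent of the tested members of each gene list called higher or lower in knockout against wild-type NPC, with the number tested in brackets. Neuron, neural progenitor, Notch and Hox 6 to 13 genes were mostly lower, and endothelial and blood, mesoderm and cell cycle genes mostly higher.

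The other 14 lists were not called. In the general pluripotency list, 1 rose and 2 fell of 15 (adjusted over the list alone, 0 and 1; camera adjusted p = 0.390), and in the naive list, 3 rose and 1 fell of 12 (adjusted over the list alone, 3 and 1; camera adjusted p = 0.554). Pou5f1 (2.26 ± 0.764 in wild type, 1.67 ± 0.385 in knockout) and Nanog (2.11 ± 1.06 and 1.98 ± 0.105) did not pass (adjusted p = 0.268 and 0.962), although Nanog was called higher (0.34, adjusted p = 0.0277) without wild-type NPC replicate 1 and lower (-0.38, adjusted p = 0.0206) without wild-type NPC replicate 2. Formative and primed genes went both ways, as 2 rose and 3 fell of 10 (adjusted over the list alone, 2 and 3; camera adjusted p = 0.287), with Zic2 falling (-3.53 ± 0.13). In the PRC1-AUTS2 complex, 1 rose and 3 fell of 13 (adjusted over the list alone, 1 and 3; camera adjusted p = 0.390). There Auts2 fell, Rybp rose (0.72 ± 0.08), and the falls of Fbrsl1 (-0.53 ± 0.13) and Ring1 (-0.39 ± 0.10) were lost without any of the 4 NPC libraries (adjusted p 0.0515 to 0.119 and 0.0857 to 0.119). Pcgf3, Pcgf5 and Rnf2 did not pass (adjusted p = 0.128, 0.159 and 0.651). Of the other Polycomb subunits, 5 rose and 3 fell of 29 (adjusted over the list alone, 5 and 3; camera adjusted p = 0.948), with Rbbp7 higher (0.56 ± 0.06) and Kdm2b lower (-0.48 ± 0.08). Of the WDR68-binding kinases and the CUL4 ligase, 2 rose and 0 fell of 8 (adjusted over the list alone, 3 and 1; camera adjusted p = 0.331), with Map3k1 higher (1.28 ± 0.15).

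Among retinoic acid response genes, 3 rose and 7 fell of 16 (adjusted over the list alone, 3 and 8; camera adjusted p = 0.0982), and Crabp2 (-2.52 ± 0.22) and Cyp26a1 (-2.01 ± 0.17) fell. In the definitive endoderm list, 4 rose and 3 fell of 9 (adjusted over the list alone, 5 and 4; camera adjusted p = 0.948), with Cxcr4 lower (-1.96 ± 0.21) and Cldn4 higher (1.06 ± 0.09). In the extraembryonic endoderm list, 7 rose and 5 fell of 17 (adjusted over the list alone, 7 and 6; camera adjusted p = 0.390), with Gata4 (2.95 ± 0.24) and Gata6 (1.40 ± 0.16) higher. For trophoblast genes, 2 rose and 0 fell of 7 (adjusted over the list alone, 2 and 0; camera adjusted p = 0.331), with Krt8 higher (0.76 ± 0.11). Germline genes gave 0 rose and 0 fell of 11 (adjusted over the list alone, 0 and 0; camera adjusted p = 0.578), the smallest p being that of Sycp3 (0.47 ± 0.14, adjusted p = 0.0510). Imprinted genes went both ways, as 6 rose and 4 fell of 20 (adjusted over the list alone, 8 and 5; camera adjusted p = 0.554), and Cdkn1c, Grb10 (-3.20 ± 0.16) and Igf2r (-1.69 ± 0.11) fell. For FGF-ERK targets, 4 rose and 2 fell of 14 (adjusted over the list alone, 5 and 2; camera adjusted p = 0.258), with Dusp4 lower (-2.22 ± 0.17) and Phlda1 higher (0.85 ± 0.11). In the astrocyte and oligodendrocyte list, 1 rose and 0 fell of 5 (adjusted over the list alone, 1 and 0; camera adjusted p = 0.948), with Pdgfra higher (1.20 ± 0.12). Median and mean had opposite signs for the imprinted (0.23 and -0.26), definitive endoderm (0.50 and -0.18) and astrocyte and oligodendrocyte (-0.15 and 0.15) lists.

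Genes of chromosome 11 stood apart from those of other chromosomes in knockout NPC, an observation made after the values were seen. Their median log2 change was 0.20 over 1107 genes, against -0.01 to 0.06 on each of the other chromosomes, and 28.2% of them were called higher, against 13.5% elsewhere. In knockout ESC the median of chromosome 11 was 0.03, against -0.04 to 0.00 elsewhere. Without chromosome 11, 1650 genes were called higher and 1579 lower in knockout NPC.

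**Figure D3:**
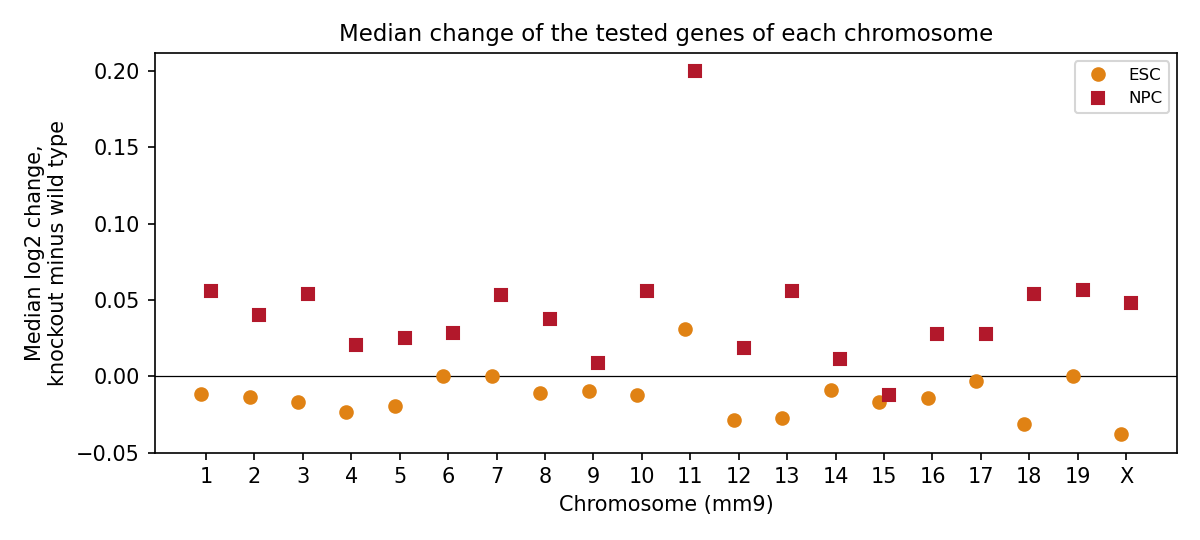
Median log2 change of the tested genes of each chromosome, knockout against wild type, with circles for ESC and squares for NPC. Chromosome 11 lay at 0.20 in NPC, above every other chromosome.

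Wild-type NPC were compared with wild-type ESC to place the differentiation itself. All 27 genes of the general and naive pluripotency lists fell, and 22 of 23 neural progenitor genes and all 15 of Hox groups 1 to 5 rose (adjusted p = 0.0252 with an estimated correlation for each list). Of 13318 genes, 9675 changed, 5538 higher and 4137 lower, 4718 of them by 2-fold or more. With quantile normalization 4578 were higher and 4735 lower, so the side with more genes depended on the scaling. Quantile normalization moved the median change of all genes from 0.15 to -0.01 in wild type, and from 0.17 to 0.00 in knockout, so changes of that size depend on the scaling. Pou5f1 went from 813 ± 36.1 to 2.26 ± 0.764 (-7.98 ± 0.16, adjusted p = 1.4e-07), Nanog by -7.15 ± 0.20 and Dppa5a by -8.68 ± 0.45. The other large falls were in Tdgf1 (-8.15 ± 0.19), Trh (-8.11 ± 0.13), Zfp42 (-8.01 ± 0.20), Tdh (-7.49 ± 0.15) and L1td1 (-6.98 ± 0.23). H19 rose from 0.607 ± 0.518 to 458 ± 17.8 (8.19 ± 0.20) and Igf2 by 7.25 ± 0.24, and Cyp26b1 (7.38 ± 0.16), Nrep (7.14 ± 0.17), Hoxb2 (7.01 ± 0.09), Hoxa5 (6.75 ± 0.23) and the Hox noncoding RNA genes Hoxb5os (7.94 ± 0.19) and Hotairm1 (6.77 ± 0.55) followed. Pax6 (3.59 ± 0.14), Nes (3.37 ± 0.11), Tubb3 (2.05 ± 0.20) and Auts2 (2.62 ± 0.12, from 1.51 ± 0.289 to 14.4 ± 0.425) rose, and Sox2 fell (-1.51 ± 0.20) to 34.2% of its ESC level. Pcgf3 rose (from 11.7 ± 0.354 to 24.5 ± 0.690), Pcgf5 fell (-1.18 ± 0.28) and the small rise of Rnf2 (0.24 ± 0.06) was lost without wild-type ESC replicate 2 (adjusted p 0.0201 to 0.0555).

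Camera called 15 lists in wild type, 6 of which held with an estimated correlation. All 15 general and all 12 naive pluripotency genes fell (camera adjusted p = 7.1e-10, and adjusted p = 0.0252 with an estimated correlation, and camera adjusted p = 2.4e-08, and adjusted p = 0.0252 with an estimated correlation). In the neural progenitor list 22 of 23 rose and 0 fell (camera adjusted p = 1.0e-07, and adjusted p = 0.0252 with an estimated correlation), and in Hox groups 1 to 5 15 of 15 rose and 0 fell (camera adjusted p = 2.4e-08, and adjusted p = 0.0252 with an estimated correlation). Imprinted genes rose in 18 of 20 cases (camera adjusted p = 1.6e-05, and adjusted p = 0.0444 with an estimated correlation) and cell cycle genes fell in 17 of 22 (camera adjusted p = 5.8e-05, and adjusted p = 0.0444 with an estimated correlation). The calls of 9 lists were lost. Among neuronal genes 23 of 25 rose and 1 fell (camera adjusted p = 2.7e-07, and adjusted p = 0.117 with an estimated correlation), among synapse and axon guidance genes 15 of 18 rose and 1 fell (camera adjusted p = 8.1e-05, and adjusted p = 0.0622 with an estimated correlation), and among retinoic acid response genes 14 of 16 rose and 1 fell (camera adjusted p = 1.1e-05, and adjusted p = 0.104 with an estimated correlation). In Hox groups 6 to 13 13 of 16 rose and 3 fell (camera adjusted p = 0.0033, and adjusted p = 0.243 with an estimated correlation), in the neural crest list 11 of 13 rose and 2 fell (camera adjusted p = 0.0064, and adjusted p = 0.300 with an estimated correlation) and in the mesoderm list 9 of 11 rose and 2 fell (camera adjusted p = 0.0336, and adjusted p = 0.150 with an estimated correlation). Notch targets rose in 9 of 11 cases (camera adjusted p = 7.9e-04, and adjusted p = 0.0697 with an estimated correlation). Feeder fibroblast genes, such as Col3a1 (5.60 ± 0.14), rose in all 15 (camera adjusted p = 3.6e-05, and adjusted p = 0.147 with an estimated correlation). Col3a1 stood at 0.0398 in wild-type ESC and 49.4 in wild-type NPC. As all 15 rose on differentiation, these genes do not mark feeder cells alone in NPC. Germline genes fell in 9 of 11 cases (camera adjusted p = 0.0013, and adjusted p = 0.0713 with an estimated correlation). Counts adjusted over the list alone were within 1 gene of these. The lowest camera adjusted p of the 14 uncalled lists was 0.186, for extraembryonic endoderm, and median, mean and test direction differed in sign for the cardiac muscle, WDR68-binding, Wnt, FGF-ERK and hypoxia lists.

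Knockout NPC were compared with knockout ESC to see how far knockout cells differentiate. All 27 genes of the general and naive pluripotency lists fell, and all 15 of Hox groups 1 to 5 rose (adjusted p = 0.0325 with an estimated correlation for each list). In the neuronal list, which was not called, 13 of 25 rose and 5 fell (camera adjusted p = 0.405). In all, 9366 genes changed, 5537 higher and 3829 lower, 4401 of them by 2-fold or more. With quantile normalization 4490 were higher and 4396 lower, a smaller excess of rises. Pou5f1 fell from 849.9 ± 12.3 to 1.67 ± 0.385 (-8.32 ± 0.16, adjusted p = 1.1e-07), and Nanog (-7.11 ± 0.20), Dppa5a (-9.27 ± 0.45), Trh (-8.63 ± 0.13), Spp1 (-8.40 ± 0.30), Zfp42 (-7.77 ± 0.20), Tdh (-7.75 ± 0.15), Tdgf1 (-7.54 ± 0.19) and Dnmt3l (-7.18 ± 0.11) fell too. H19 (9.17 ± 0.20), Igf2 (8.83 ± 0.24), Hba-x (8.60 ± 0.16), Hbb-y (7.63 ± 0.19), Hbb-bh1 (7.31 ± 0.36), Igfbp5 (7.19 ± 0.11) and Hoxa5 (7.11 ± 0.23) rose. The short RNA gene Scarna10 was listed at 0 in knockout ESC and lost its call without any of the 4 knockout libraries (adjusted p 0.0593 to 0.105). Tubb3 fell (-2.41 ± 0.20), as did Stmn2 (-5.09 ± 0.12) and Sox2 (-4.85 ± 0.20). Pax6 (1.58 ± 0.14), Nes (2.71 ± 0.11) and Auts2 (1.72 ± 0.12) rose, as did Pcgf3 (0.57 ± 0.11) and Rnf2 (0.27 ± 0.06), and Pcgf5 did not pass (adjusted p = 0.932).

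Camera called 15 lists in knockout, 3 of which held with an estimated correlation. All 15 general and all 12 naive pluripotency genes fell (camera adjusted p = 3.3e-11, and adjusted p = 0.0325 with an estimated correlation, and camera adjusted p = 6.6e-09, and adjusted p = 0.0325 with an estimated correlation), and all 15 genes of Hox groups 1 to 5 rose (camera adjusted p = 5.0e-08, and adjusted p = 0.0325 with an estimated correlation). In the neural progenitor list 15 of 23 rose and 2 fell (camera adjusted p = 0.0075, and adjusted p = 0.121 with an estimated correlation). Neuronal genes were not called as a list, as 13 of 25 rose and 5 fell (camera adjusted p = 0.405), and the same held for Notch targets, of which 6 of 11 rose and 1 fell (camera adjusted p = 0.225), and neural crest genes, of which 9 of 13 rose and 2 fell (camera adjusted p = 0.184). Among retinoic acid response genes 15 of 16 rose and 1 fell (camera adjusted p = 2.4e-05, and adjusted p = 0.134 with an estimated correlation), among synapse genes 13 of 18 rose and 2 fell (camera adjusted p = 0.0123, and adjusted p = 0.134 with an estimated correlation) and in Hox groups 6 to 13 11 of 16 rose and 3 fell (camera adjusted p = 0.0249, and adjusted p = 0.356 with an estimated correlation). Among mesoderm genes 9 of 11 rose and 2 fell (camera adjusted p = 0.0184, and adjusted p = 0.134 with an estimated correlation), among endothelial and blood genes 10 of 11 rose and 1 fell (camera adjusted p = 0.0054, and adjusted p = 0.134 with an estimated correlation) and among extraembryonic endoderm genes 13 of 17 rose and 3 fell (camera adjusted p = 0.0490, and adjusted p = 0.242 with an estimated correlation). Feeder fibroblast genes gave 12 rises and 1 fall of 15 (camera adjusted p = 0.0054, and adjusted p = 0.298 with an estimated correlation), and imprinted genes 14 rises and 3 falls of 20 (camera adjusted p = 0.0054, and adjusted p = 0.121 with an estimated correlation). Falls outnumbered rises among germline (9 and 1 of 11, camera adjusted p = 0.0019, and adjusted p = 0.121 with an estimated correlation), cell cycle (15 and 4 of 22, camera adjusted p = 0.0052, and adjusted p = 0.121 with an estimated correlation) and hypoxia genes (9 and 3 of 13, camera adjusted p = 0.0397, and adjusted p = 0.454 with an estimated correlation). Counts adjusted over the list alone were within 1 gene of these. The hypoxia call was lost with median-ratio scaling (adjusted p = 0.0507), and those of Hox groups 6 to 13 (0.0530) and extraembryonic endoderm (0.0779) with a pseudocount of 0.1. Median, mean and test direction differed in sign for the other Polycomb subunits and FGF-ERK targets.

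Across all genes, the response in knockout was about as large as in wild type. The major-axis slope of the knockout change on the wild-type change was 0.962 over 13318 genes (0.922 to 0.993 with each library left out in turn), with r = 0.834 across genes. Both genotypes raised 4612 genes, against 2302 by chance, and lowered 3265, against 1189 by chance, and 156 genes changed in opposite directions. Genes called higher in wild type had a median change of 1.08 there and 0.97 in knockout, and genes called higher in knockout 1.01 there and 0.95 in wild type. Genes called lower in wild type had medians of -0.88 there and -0.75 in knockout, and genes called lower in knockout -0.85 there and -0.89 in wild type.

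**Figure D4:**
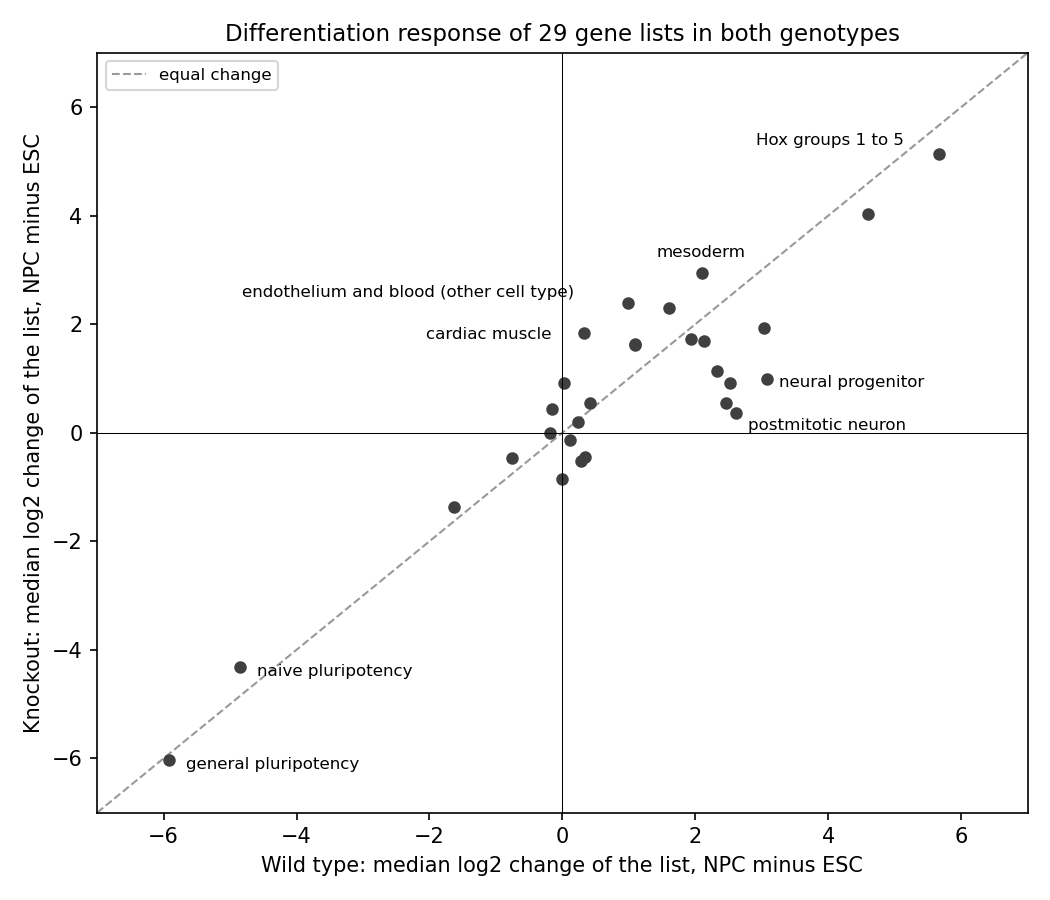
Median log2 change from ESC to NPC of each gene list, wild type on the horizontal axis and knockout on the vertical axis, with a dashed line where both are equal. Pluripotency lists lay near the line, and the neuron list lay at 2.61 in wild type and 0.37 in knockout.

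Whether the knockout effect differs between stages was tested directly, gene by gene, which is the same as asking whether differentiation differs between genotypes. In the neural progenitor list 19 of 23 genes were more negative in NPC, a call that held (adjusted p = 0.0294 with an estimated correlation). The effect differed in 2237 genes, 1120 more positive in NPC and 1117 more negative, and in 1052 of them by 2-fold or more, 350 and 702. With median-ratio scaling the count was 2075, with 814 more positive and 1261 more negative. The count was 1415 without wild-type ESC replicate 1, 1430 without wild-type ESC replicate 2, 1358 without knockout ESC replicate 1, 1283 without knockout ESC replicate 2 and 1414 without knockout NPC replicate 1. The differences were -4.46 ± 0.28 for Tubb3 (adjusted p = 2.4e-04), -3.33 ± 0.28 for Sox2 (adjusted p = 6.1e-04), -2.01 ± 0.20 for Pax6 (adjusted p = 0.0011), -0.90 ± 0.17 for Auts2 (adjusted p = 0.0126) and 3.72 ± 0.27 for Foxf1 (adjusted p = 3.9e-04). Pou5f1, Nanog, Pcgf3, Pcgf5 and Rnf2 did not pass (adjusted p = 0.368, 0.950, 0.0979, 0.0929 and 0.826).

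Of the neural progenitor genes, 19 of 23 were more negative and 2 more positive (adjusted over the list alone, 19 and 2), and of the neuronal genes, 22 of 25 were more negative and 1 more positive (adjusted over the list alone, 23 and 2; for neuronal genes adjusted p = 0.0504 with an estimated correlation). Notch targets gave 7 of 11 more negative and 0 more positive (adjusted over the list alone, 7 and 0; adjusted p = 0.0504 with an estimated correlation), and Hox groups 6 to 13 10 of 16 more negative and 3 more positive (adjusted over the list alone, 11 and 3; adjusted p = 0.129 with an estimated correlation). Endothelial and blood genes gave 0 of 11 more negative and 8 more positive (adjusted over the list alone, 0 and 8; adjusted p = 0.0504 with an estimated correlation), mesoderm genes 1 of 11 more negative and 8 more positive (adjusted over the list alone, 1 and 8; adjusted p = 0.120 with an estimated correlation) and cardiac muscle genes 0 of 7 more negative and 4 more positive (adjusted over the list alone, 0 and 4; adjusted p = 0.0970 with an estimated correlation). Cell cycle genes gave 0 of 22 more negative and 9 more positive (adjusted over the list alone, 0 and 11; adjusted p = 0.0504 with an estimated correlation). Camera called 16 lists, and that of neural progenitors alone held with an estimated correlation (camera adjusted p = 1.2e-13, and adjusted p = 0.0294 with an estimated correlation). Fry called 24 of the 29. The lowest camera adjusted p of the 13 uncalled lists was 0.0587, for imprinted genes, and the germline list (camera adjusted p = 0.0647) passed with median-ratio scaling (0.0248). With a pseudocount of 0.1 the calls of mesoderm genes (adjusted p = 0.106) and of Hox groups 1 to 5 (0.145) were lost. Median, mean and test direction differed in sign for the definitive endoderm, PRC1-AUTS2, and astrocyte and oligodendrocyte lists.

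Few genes passed for the knockout effect in both ESC and NPC. Rec8, Peg10 and Pik3r3 rose in both stages (3 genes, against 2.50 by chance), and Dcaf7 and Grb10 fell in both (2 genes, against 2.03 by chance). Psors1c2 fell in ESC and rose in NPC. Pik3r3 and Psors1c2 were named after their values were seen. Rec8 rose by 1.19 ± 0.10 in ESC and 2.52 ± 0.10 in NPC, where it went from 11.1 ± 1.19 to 68.5 ± 1.31, and Peg10 rose by 1.19 ± 0.11 and 1.16 ± 0.11. Pik3r3 rose by 0.66 ± 0.08 and 0.39 ± 0.08, and the changes of Grb10 were -1.32 ± 0.16 and -3.20 ± 0.16. The number shared in direction, 5, was 2 without wild-type ESC replicate 1, wild-type ESC replicate 2 or knockout ESC replicate 2. Across all genes the log2 changes of the 2 stages correlated at r = 0.06.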

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

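The tests of undifferentiated cells, of scaling and of chance overlap, and those of part of chromosome 11 and of an extra copy, were chosen after the results were seen; the tests of feeder cells, of chromosome regions and of low fragment numbers for imprinted genes, and of matched genes for chromosome 11 were written before their values were seen. Chromosome 11 was picked after looking at 20 chromosomes in 2 comparisons, and its values by chromosome and bin were known when the test of matched genes was written. It took the place of short RNA genes, weighed earlier against few fragments and met by their median of 2.50 implied fragments.

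The knockout effect differed between NPC and ESC, by a test of the difference itself, in 2237 genes. The largest positive differences among named genes were in Foxf1 (3.72 ± 0.27, adjusted p = 3.9e-04), Fendrr (3.51 ± 0.24, adjusted p = 3.2e-04), Grin2c (3.43 ± 0.20, adjusted p = 2.2e-04), Sh3bgr (3.24 ± 0.23, adjusted p = 3.6e-04), Hba-x (3.18 ± 0.23, adjusted p = 3.5e-04), Gata4 (3.11 ± 0.34, adjusted p = 0.0016) and Sel1l3 (2.98 ± 0.19, adjusted p = 2.6e-04). That of Rnu11 (8.64 ± 2.12, adjusted p = 0.0338) rests on zeros in all but 3 libraries. The largest negative differences were in Miat (-5.01 ± 0.45, adjusted p = 8.5e-04), Msx3 (-4.93 ± 0.59, adjusted p = 0.0025), Tagln3 (-4.82 ± 0.44, adjusted p = 8.7e-04), Ckb (-4.76 ± 0.19, adjusted p = 1.1e-04), Igfbpl1 (-4.61 ± 0.35, adjusted p = 4.0e-04), Stmn2 (-4.50 ± 0.16, adjusted p = 9.1e-05), Tubb3 (-4.46 ± 0.28, adjusted p = 2.4e-04) and Fez1 (-4.45 ± 0.25, adjusted p = 2.2e-04). Auts2 (-0.90 ± 0.17, adjusted p = 0.0126), Sox2 (-3.33 ± 0.28, adjusted p = 6.1e-04) and Pax6 (-2.01 ± 0.20, adjusted p = 0.0011) differed too. The difference of Nes (-0.66 ± 0.16, adjusted p = 0.0307) was lost without any 1 of 7 of the 8 libraries, wild-type ESC replicate 1 being the exception (adjusted p 0.0328 to 0.0999), and that of Rnu11 without 6 of them, the exceptions being the wild-type ESC libraries (0.002 to 0.107).

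The same difference was called in 16 gene lists, 1 of which, neural progenitors (camera adjusted p = 1.2e-13, and adjusted p = 0.0294 with an estimated correlation), held with an estimated correlation. Those more negative in NPC were postmitotic neurons (camera adjusted p = 2.0e-21, and adjusted p = 0.0504 with an estimated correlation), synapse and axon guidance (camera adjusted p = 0.0093, and adjusted p = 0.129 with an estimated correlation), retinoic acid response (camera adjusted p = 0.0085, and adjusted p = 0.224 with an estimated correlation), Hox groups 1 to 5 (camera adjusted p = 0.0033, and adjusted p = 0.0970 with an estimated correlation), Hox groups 6 to 13 (camera adjusted p = 6.2e-05, and adjusted p = 0.129 with an estimated correlation) and neural crest (camera adjusted p = 5.2e-04, and adjusted p = 0.181 with an estimated correlation). The same direction held for Wnt targets (camera adjusted p = 0.0011, and adjusted p = 0.181 with an estimated correlation), Notch targets (camera adjusted p = 1.9e-05, and adjusted p = 0.0504 with an estimated correlation), hypoxia and glycolysis (camera adjusted p = 4.9e-06, and adjusted p = 0.129 with an estimated correlation) and feeder fibroblasts (camera adjusted p = 0.0212, and adjusted p = 0.296 with an estimated correlation). More positive were mesoderm (camera adjusted p = 0.0075, and adjusted p = 0.120 with an estimated correlation), cardiac muscle (camera adjusted p = 7.8e-04, and adjusted p = 0.0970 with an estimated correlation), p53 targets (camera adjusted p = 0.0022, and adjusted p = 0.0970 with an estimated correlation), cell cycle (camera adjusted p = 2.8e-05, and adjusted p = 0.0504 with an estimated correlation) and endothelium and blood (camera adjusted p = 9.8e-07, and adjusted p = 0.0504 with an estimated correlation).

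Lower neuronal and neural progenitor genes in knockout NPC were weighed against stem cells left in the libraries, feeder cells and scaling. The 27 tested pluripotency genes stood at a median of 0.342% of their knockout ESC level (0.495% in wild type), where stem cells making up most of the RNA would need over 50%. Feeder genes had a median change of -0.37 over 15 genes (bootstrap standard error 0.42), where feeders would need one above 1. All 15 also rose on differentiation in wild type, so in NPC they do not mark feeders alone. With median-ratio scaling the neuron list had a median of -2.96. The factors were 0.988 for wild-type NPC and 1.04 to 1.05 for knockout NPC, too close together to bring such a median near 0. That result follows from the factors and is not separate evidence. A biological effect of the genotype on neural differentiation stays open as a hypothesis. So does a shift of the culture towards other cells, as 9 of 11 endothelial and blood genes rose (adjusted p = 0.0512 with an estimated correlation) and single clones may differ, which these 2 libraries per group did not test.

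Imprinted genes among the genes changed in knockout ESC were weighed against chance, altered chromosome regions and low fragment numbers. Chance was not excluded, as Fisher's exact test (two-sided p = 1.5e-07 for 4 of 20 genes, and 1.2e-05 with Peg10 and Sgce counted once) treats genes as independent and followed from these calls in 1 of 29 lists, and the list call was lost (adjusted p = 0.269 with an estimated correlation). Other genes within 5 Mb, 13 to 25 for each, had median changes of at most 0.082, where a gain of 1 copy would give up to 0.585. For Grb10, which fell, a loss would lower the neighbours, and these had a median of 0.079. A gain or loss of only a few genes would not move such medians. The lowest fragment number in the higher group was 113. These tests used calls that mostly ended when a library was left out. Chance, a loss of imprinting through passage or cloning, or an effect of WDR68 may explain the changes, and the design cannot separate them, since the number of knockout clones is not stated.

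Higher RNA of chromosome 11 genes in knockout NPC was weighed against the kind of genes it carries, a local change and an extra copy in every cell. Against genes matched on wild-type ESC level, wild-type NPC level and transcript GC content, 10 for each of 1100 genes, they were higher by a median of 0.18 (bootstrap standard error 0.0125). The standard errors in this paragraph resample genes, which are not independent replicates. They do not cover the spread between libraries or clones. The 13 bins of 10 Mb lay 0.0785 (bootstrap standard error 0.0450) to 0.384 (0.0868, over 23 genes) above the other chromosomes, 11 of them by more than 2 standard errors. The chromosome lay 0.17 above the others (standard error 0.0136), where 3 copies against 2 would give up to 0.585. A gain of the chromosome in part of the knockout cells may explain a shift of most bins, though not the height of the highest by itself. On a plain log2 scale, 24.3% of cells with 1 extra copy would give 0.17 throughout. The share would be larger here, as the 1 added to FPKM shrinks the changes of genes with low FPKM. Knockout ESC showed 0.0447 (standard error 0.00601). A gain in part of the cells remains a hypothesis, since no DNA was analysed here and regulation of many genes on the chromosome was not excluded. Nor does the comparison tell a gain in knockout NPC from a loss in wild-type NPC. Dcaf7, the gene labelled as knocked out, lies on the same chromosome, and whether its targeting is linked to the shift was not tested.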

How the results depend on the processing

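The alternative without short RNA genes and the imprinted list with Peg10 and Sgce counted once were chosen after the results were seen. Under the other alternatives, counts stayed within 1.5 times the value reported except as follows. The count in knockout ESC (33) was 3 in a fit of only these groups, 15 with the replicate number as a block (14 of them among the 33), 19 at a 2-fold minimum and 10 to 16 with each library left out. At a 2-fold minimum the counts were 1038 in knockout NPC (3648), 4718 on differentiation in wild type (9675), 4401 in knockout (9366) and 1052 for the difference between stages (2237). Leaving out libraries gave 2281 to 2743 genes in knockout NPC, 8727 to 8841 and 8317 to 8455 on differentiation, and 1283 to 1822 for the difference. The slope of the response (0.962) ranged from 0.922 to 0.993. The 5 genes changed alike in both stages became 3 without the filter, 3 with quantile normalization, 8 without short RNA genes and 2 to 5 with libraries left out. A stricter minimum lowers the counts by construction, and fewer libraries or degrees of freedom leave less power. The calls themselves also differed, as none of the 3 genes from the fit of only the ESC groups was among the 33. The cause of these and the other shifts was not tested.

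With the replicate number as a block the other counts were 3423, 9632, 9309 and 2070, and correlations of replicate deviations between groups of -0.05 to 0.18 gave no sign that the numbers pair libraries. Without short RNA genes, 47 genes changed in knockout ESC, 26 of them among the 33. Of the tests of 29 lists in 5 contrasts, 52 lost their call with an estimated correlation and 42 gained one with fry, and pseudocount, scaling and block changed 8, 4 and 2. For named genes, 8176 values were computed, of which 407 lost a call, 17 gained one, 13 uncalled values changed sign and 1 call appeared with the opposite sign, that of Nanog in NPC (0.34 without wild-type NPC replicate 1, with a range of -0.38 to 0.34 over the libraries left out).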

Other observations

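Small RNA genes made up 41.4% of the summed FPKM in knockout ESC replicate 1 and 33.6% in replicate 2, and the called microRNA and small nucleolar RNA genes rested on 0.495 to 23.4 implied fragments in the higher group, with a median of 2.50. A test of few fragments as the source of these calls was written and run first, the median met what it asked for, and chromosome 11 was then weighed in its place after the data were seen. The 45S ribosomal RNA gene Rn45s stood at 6868 and 6331 in the knockout NPC libraries, against 8913 and 9559 in wild-type NPC and 8481 to 9252 in ESC (log2 change in NPC -0.49 ± 0.12, adjusted p = 0.0229), and what lowered it was not tested. Per library, chromosome 11 genes in knockout NPC lay 0.17 and 0.18 above the other chromosomes.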
